A study of Homo sapiens with 4 samples.

How the data were processed

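Chromatin from IMR90 human lung fibroblasts was crosslinked with formaldehyde, sheared to fragments of about 500 bp and precipitated with an antibody against macroH2A1, per the labels' protocols. There were 2 ChIP replicates and 2 inputs, sequenced on an Illumina instrument. The submitters' processing notes name CASAVA 1.7 and the genome build hg19. The aligner, the treatment of duplicate reads, the segmentation program and the scaling between ChIP and input are not given in the sources used here. Each ChIP replicate had a file of its own, so the replicates were not pooled, and the inputs were used only as the authors' denominator. No read counts were given in these files, so the depth is unknown, and no counting interval could be made.

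The deposited files are genome segmentations and not lists of called peaks. Segments tile each chromosome. A segment can hold several blocks separated by gaps of over 1000 bases (21846 such gaps in replicate 1 and 36348 in replicate 2), and 86.9% and 64.9% of segments were a single block. Replicate 1 held 46952 segments and replicate 2 held 25584. The authors give each segment a deposited log2 ratio of ChIP over input. The base of the logarithm was inferred from the values: 2 raised to the value averaged 1.01 and 0.995 over assayed bases, and e raised to it 1.15 and 1.12. The authors also give each segment a deposited −log10 p-value. It was read as one-sided in the direction of the ratio, because its median was 0.32 and 0.31 where the log2 ratio was near 0. It reaches a numerical ceiling of at least 307, and 68.5% and 68.6% of the segments with a log2 ratio below 0 list it as 0, so it was used only to select enriched segments. The segment value is a mean over a long stretch, so short peaks or dips inside a segment are not seen. Because mean ratios are close to 1, the values are relative within a library and show no absolute amount of macroH2A1.

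The design fixed before the data were examined assumed called peaks. As the files hold segmentations, a region was taken as an enriched segment, with log2 ratio above 0 and −log10 p of at least 2. Bases in blocks of both replicates (2748 Mb) became the denominator and the space for shifts, in place of megabases holding a region, which were run as an alternative. Coordinates in the files and in the reference, GRCh37 with GENCODE release 44 mapped to it, are of the same build. The mitochondrial sequence differs (16571 against 16569 bases) and was left out, as were chromosome Y and all genes on it. Coordinates are printed counting from 1.

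Intervals were intersected exactly, and overlap and annotation were tested in bins of 1 kb against 10000 circular shifts within each chromosome, with two-sided p-values, the smallest being 0.0002. For GC content and for gene lists under shifts there were 1000 shifts. Of 20090 protein-coding genes, the 19511 with at least 50% of their span assayed were measured, and a gene was its annotated span, so a long read-through model counts whole. The 18 gene lists were fixed before the data were examined, and 1 listed symbol was not found. A list's median covered share was compared with 10000 random lists drawn in 20 length bins, with Benjamini-Hochberg adjustment over the 18 lists and a threshold of 0.05. Named genes were chosen by a rule fixed beforehand: per list the 2 members with the highest and the 2 with the lowest covered share, ties by symbol, the 10 genes with the most covered bases, and the 10 longest shared domains. As ties are broken alphabetically, many of the genes named at 100% or 0 share that value with others. Some genes that the rule names are not reported here. The alternatives were whole segments with their gaps, stricter thresholds, other overlap rules and denominators, a 5-kb window at the start site, circular shifts, each replicate alone, autosomes only, the mean in place of the median, GC matching and the mean log2 ratio. These nulls describe the placement of regions in these libraries and not the sampling of cultures.

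The procedures were tested on simulated data. Of 100 pairs of unrelated placements, 6% gave p under 0.05 in the overlap test, and of 100 random lists of 30 genes, 5% did so by the mean. With 15 of 30 genes set to full coverage, 100% of lists were recovered, also by the mean. The planned median was not run on these random lists. Here and in the shifts below, a call was an unadjusted p under 0.05, with fewer random lists than in the main test. These rates are therefore not those of the adjusted calls. On shifted regions, where no list is special, length matching called families in clusters far too often by the mean: 73% of 100 shifts for protocadherins, 67% for clustered histone genes, 60% for HOX and for zinc finger genes, 49% for keratin-associated proteins and 48% for olfactory receptors. By the median the HOX list was called in 18%. The senescence secretory list was called in 12% by the mean and 3% by the median, the epithelial list in 9% and 4%, and the fibroblast list in 9% and 3%. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.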

Results

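MacroH2A1, a variant of histone H2A that carries a large additional macro domain, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in IMR90 human lung fibroblasts. The series held 4 samples: 2 ChIP replicates, which the labels describe as biological replicates, and 2 corresponding inputs. Each ChIP replicate had a deposited genome segmentation with a log2 ratio of ChIP over input and a significance value per segment, and the inputs entered only through that ratio. Read depth was not given in the files, so counting error is unknown, and the error of each value below is the spread between the 2 replicates. A segment was called enriched when its log2 ratio was above 0 and its −log10 p was at least 2. The covered share of a gene, chromosome or annotation class was the percent of its assayed bases that lay in enriched segments of both replicates. The comparisons ask where in the genome macroH2A1 lies, how well the replicates match, and which chromosomes and genes are covered.

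MacroH2A1 occupied broad stretches of the assayed genome, with 35.5% of 2788 Mb enriched in replicate 1 and 33.4% of 2756 Mb in replicate 2. Enriched segments had a median length of 27.1 kb in replicate 1 (19301 segments) and 51.6 kb in replicate 2 (10374 segments), and their median log2 ratio was 0.82 and 0.85. All segments together had medians of 27.4 and 53.7 kb, so enriched segments were no longer than segments in general. These lengths depend on the segmentation of each replicate. The replicates shared 814 Mb, which formed 13649 domains after pieces within 1 kb were joined. Of the shared bases, 62.7% lay in the 2478 domains of 100 kb or more. Shared bases made up 75.3% of the bases enriched in either replicate (Jaccard index). Shifting one replicate around each chromosome gave 22.7% on average, and 95% of 10000 shifts fell between 21.5% and 24.1% (two-sided circular-shift permutation test, p = 0.0002, the smallest these shifts can give). With as many of the strongest segments from replicate 1 as replicate 2 held, the Jaccard index was 43.0%, against 12.6% for shifts. That setting sets 417 Mb of replicate 1 against 918 Mb of replicate 2, and 96.2% of those replicate 1 bases were shared. Segments of replicate 1 overlapped replicate 2 by at least 1 base in 87.2% of cases, and those of replicate 2 overlapped replicate 1 in 96.5%. When 50% of both segments had to overlap the shares were 32.7% and 60.8%. Across 2748208 bins of 1 kb the log2 ratios of the replicates had a Pearson r of 0.90 and a Spearman rho of 0.90; these are correlations across bins, which are not independent. The log2 ratio had opposite signs in 9.30% of bins.

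Chromosome X was covered far more than any autosome. Enriched segments of both replicates covered 66.9% of chromosome X and 27.6% of the autosomes as a whole. Individually the replicates covered 75.4% and 69.4% of chromosome X (72.4% ± 4.20, SD, n = 2). Among the 22 autosomes the shared share ran from 20.8% on chromosome 16 to 32.7% on chromosome 17, with a mean of 27.2% ± 3.10 (SD over 22 autosomes). Chromosome X ranked first in both replicates, and it was the only chromosome of the 23 with a mean log2 ratio above 0, at 0.37 ± 0.09 (SD, n = 2). Chromosome 19, the most gene-dense at 27.2 protein-coding genes per Mb, had the lowest mean log2 ratio, -0.77 ± 0.09 (SD, n = 2), and a covered share of 20.9%. Chromosome 7 also lay low, at 22.1%. With the stronger 50% of segments by the authors' own value, chromosome X was covered to 15.2% and the autosomes to 8.71%, so the ratio of X to autosomes was 1.75 in place of 2.42. The series has no other group of samples, so no test between samples was made for the chromosomes.

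**Figure D1:**
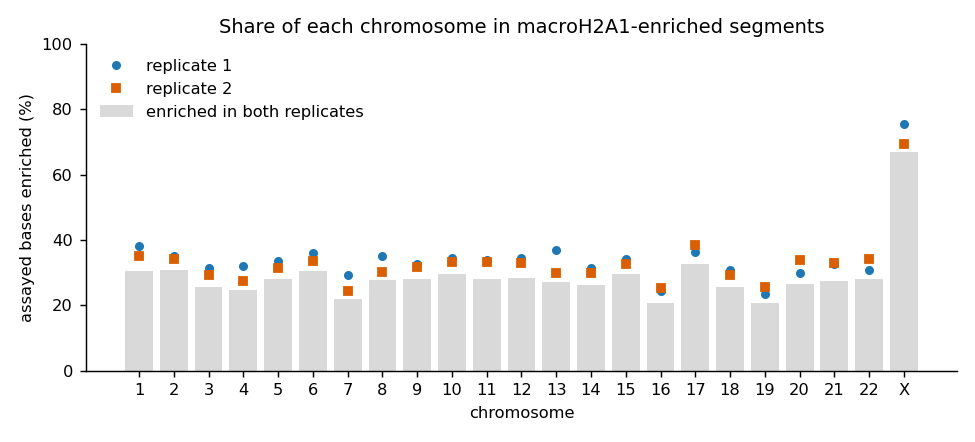
Percent of assayed bases in enriched segments (vertical axis) for the 22 autosomes and chromosome X (horizontal axis). Bars show bases enriched in both replicates, circles replicate 1 and squares replicate 2. Chromosome X stands at 66.9% and the autosomes between 20.8% and 32.7%.

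Chromosome X differed from the autosomes in its lowest bins far more than in its highest. In the 1-kb bins of replicate 1, the 5th percentile of the log2 ratio was -0.54 on chromosome X and -2.09 on autosomes, whereas the 95th percentile was 1.18 and 1.14. In replicate 2 the 5th percentile was -0.63 and -2.08, and the 95th percentile 1.22 and 1.16. The median bin was at 0.56 and 0.34 on chromosome X in the 2 replicates, against -0.39 and -0.44 on autosomes. Of the 10 protein-coding genes with the most covered bases, 4 lay on chromosome X and were covered to 100%. They were IL1RAPL2 (X:103810880-105011822, hg19; log2 ratio 0.91 ± 0.13, SD, n = 2), DIAPH2 (X:95939711-96859996; 0.52 ± 0.24), PCDH11X (X:91034260-91878229; 0.40 ± 0.30) and the gene model ENSG00000250349 (X:37208583-38546928; 0.76 ± 0.06).

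**Figure D2:**
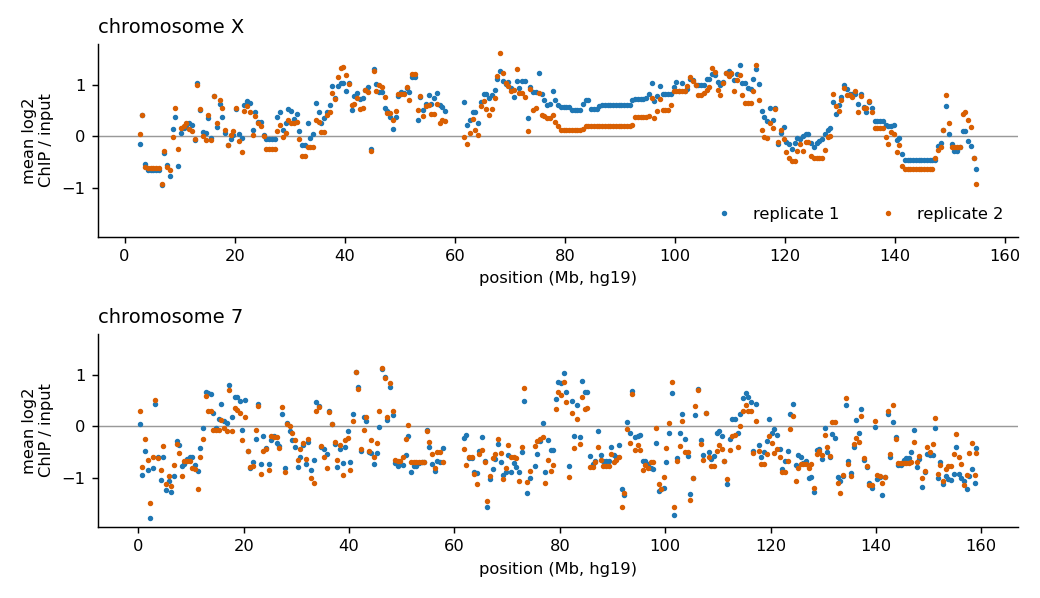
Mean log2 ratio of ChIP over input (vertical axis) in 500-kb windows along chromosome X and chromosome 7 (horizontal axis, Mb, hg19), with a point per window and replicate. The mean over the chromosome was 0.37 on chromosome X and -0.41 on chromosome 7. Chromosome 7 ranked 21 of 23 chromosomes by covered share and so lies low among the autosomes.

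The longest shared domains held few genes, and 6 of the 10 overlapped no protein-coding gene. The longest ran over 1587 kb at 21:28340426-29927107 and overlapped no protein-coding gene, with a log2 ratio of 0.84 ± 0.15 (SD, n = 2). The next, of 1465 kb at 6:139537450-141002797, held TXLNB and CITED2, a transcriptional co-regulator, at 0.93 ± 0.10. Domains of 913 kb (22:27226370-28139026), 887 kb (20:10656697-11543996), 871 kb (7:45989251-46860617), 868 kb (2:52271679-53139485) and 858 kb (16:64114148-64971722) overlapped no protein-coding gene either. The other 3 of the 10 longest were an 854-kb domain on chromosome X (X:35335022-36188622) with MAGEB16 and part of CFAP47, an 840-kb domain with TMEM26 and CABCOCO1 (10:62817613-63657931), and an 820-kb domain with GADL1 (3:30750110-31570061). The autosomal gene with the most covered bases was RUNX1 (21:36160098-37376965), a transcription factor of blood development. RUNX1 had 1107 kb covered, or 91.4% of its assayed bases, at a log2 ratio of 0.89 ± 0.05 (SD, n = 2). Its annotated span here was 1217 kb, and its rank by covered bases depends on that annotated model. RAD51B (84.3%), CAMTA1 (79.0%), LRMDA (67.7%), ZFPM2 (59.4%) and the neurexin gene NRXN3 (50.1%) completed the 10. ZFPM2 and NRXN3 were covered in part and their mean log2 ratios over the whole gene were -0.06 ± 0.03 and 0.06 ± 0.02.

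Sequence of annotated protein-coding genes was covered less than its share of the genome. Intergenic sequence, here all that lies outside protein-coding genes and their promoters, held 70.0% of the shared bases, 1.29 times the mean of circular shifts. Of intergenic bases, 38.7% were covered. Exons were covered to 14.7% and held 1.80% of shared bases, 0.51 times the shifts. Introns were covered to 19.5% (0.67 times) and promoters, 500 bases either side of a start site, to 22.9% (0.79 times). All 4 classes differed from 10000 shifts (two-sided circular-shift permutation test, adjusted p = 0.0002 over the 4 classes). The direction held in both replicates, which gave 0.80 and 0.89 times for promoters. Covered 1-kb bins had a median GC content of 41% and other bins 39.5%, a difference of 1.5 percentage points where the median of 1000 shifts was -0.20 (permutation p = 0.002, the smallest these shifts can give). The difference was 2.2 points in replicate 2 alone and 0.8 in replicate 1 alone. On autosomes the covered share rose from 20.4% of bins under 35% GC to 33.9% of bins with 45 to 50% GC, and was 24.8% in bins of 60% GC or more.

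Marker genes of epithelial, endothelial and immune cells and of pluripotency were covered more than genes of their length. By the median none of these calls held against circular shifts, which keep neighbouring genes together (adjusted permutation p from 0.0599 to 0.236). The 25 epithelial genes had a median covered share of 89.2%, and 15 of them were covered over at least 50% of their length. CDH1, which encodes E-cadherin (16:68771195-68869440), was covered to 100% at a log2 ratio of 0.81 ± 0.07 (SD, n = 2), and so was EPCAM (2:47572297-47614740) at 0.74 ± 0.02. ESRP2 and CLDN3 were covered to 0, at -1.78 ± 0.11 and -0.39 ± 0.02. The 12 endothelial genes had a median of 59.6%, with CDH5, the cadherin of endothelial junctions, and CLDN5 at 100% and ESAM and EMCN at 0 (EMCN at 18.5% in replicate 1). Of the 26 immune genes (median 11.6%, and 36.1% and 38% in replicates 1 and 2 alone), CD79B was at 100% and CD2 and CD3D at 0. The pluripotency list (20 genes, median 41.9%, and 69.3% in replicate 2 alone) had DNMT3L and DPPA5 at 100% and DNMT3B and DPPA2 at 0.

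Secreted factors of senescent cells, HOX genes and developmental transcription factors were covered more than genes of their length too, but not, by the median, against circular shifts (adjusted permutation p from 0.0599 to 0.512). The 35 measured genes of the senescence secretory list had a median of 79.5% (49.4% on autosomes), and 18 were covered over at least 50%. CCL2, a monocyte chemoattractant (17:32582293-32584227), had a log2 ratio of 1.40 ± 0.06 (SD, n = 2) and CCL20 one of 0.77 ± 0.10, both with 100% covered. FGF2 lay at -1.81 ± 0.24 with 0 covered, and ANGPTL4 was covered to 100% in replicate 2 and to 0 in replicate 1. The HOX genes, which pattern the body axis, had a median of 68.3% (39 genes), of which 21 were covered over at least 50% and 16 to 0. HOXA10 and HOXA11 were at 100% with a log2 ratio of 1.10 ± 0.18, and HOXA2 at 0 with -2.42 ± 1.33. Among 61 developmental transcription factors the median was 3.56% and the mean 40.6%. The median was 18.9% in replicate 1 alone and 100% in replicate 2 alone, and it was 0 on autosomes, a setting chosen after seeing the data, where the list was not past the threshold. FOXA1 (0.86 ± 0.11) and EVX2 (0.44 ± 0.03) were covered to 100%, whereas DLX5 was at 0 and DLX2 was covered in replicate 2 alone.

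By the test chosen before the data were examined, the median covered share against 10000 random lists matched on gene length, 7 of 18 lists were covered more. The cut-offs that define an enriched segment were set only once the files proved to be segmentations. These were the epithelial, HOX, senescence secretory and developmental lists (adjusted permutation p = 0.0018 each), the endothelial and pluripotency lists (0.0126 each) and the immune list (0.018), adjusted by Benjamini-Hochberg over 18 lists. With circular shifts of the regions none of the 7 kept its call by the median: adjusted permutation p = 0.0599 for the epithelial and the senescence secretory lists, 0.0629 for developmental factors, 0.158 endothelial, 0.234 immune, 0.236 pluripotency and 0.512 HOX. By the mean with circular shifts, a setting chosen after seeing the data, the epithelial list (59.5% against 27.3%, adjusted permutation p = 0.0045) and the senescence secretory list (51.5% against 27.9%, adjusted permutation p = 0.02) were covered more. The other 5 lists were not past the threshold in that setting. The settings of a −log10 p of 5 and of a log2 ratio over 0.5 were also chosen after seeing the data. In both, the HOX, senescence secretory, developmental and immune lists had a median of 0. The epithelial, endothelial and pluripotency lists stayed past the threshold there. With only the stronger segments by the authors' own value, all 7 lists had a median of 0 and none kept its call. In the 5-kb window at the start site, the immune and pluripotency lists were not past the threshold (adjusted permutation p = 0.468 and 0.152). The other 5 lists kept their calls in that window. The mean log2 ratio was -0.04 for the senescence secretory list, -0.21 for HOX and -0.004 for immune genes, so these lists did not lie above 0 on average. It was 0.07 for developmental factors, 0.21 for pluripotency, 0.30 for endothelial and 0.32 for epithelial genes. All 7 lay above length-matched random lists, whose medians ran from -0.88 to -0.81.

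Genes of the fibroblast's own matrix, ribosomal protein genes and cell cycle genes were hardly covered. Length-matched random lists had a median of 0 for these lists, so the median cannot fall below it, and the mean was compared instead, a choice made after seeing the data. The mean over all measured genes was 19.9%. The fibroblast list had a mean of 4.16% (35 genes; 9.28% and 7.04% in single replicates), with 31 at 0, among them ACTA2, a smooth muscle actin, at a log2 ratio of -1.18 ± 0.26 (SD, n = 2) and CNN1 at -1.36 ± 0.22. LUM, which encodes the matrix proteoglycan lumican (12:91496406-91505271), was the exception at 100% and 0.88 ± 0.11, and COL5A2 was covered to 23.5%. Ribosomal protein genes had a mean of 1.80% (51 genes, 49 at 0; 4.84% in replicate 2 alone), with RPL11 at -1.96 ± 0.81 and RPL10A at -1.81 ± 0.25. RPS9, with an annotated span of 48.2 kb, was covered to 66.4% and RPL15 to 25.6%. Cell cycle genes had a mean of 2.69% (33 genes, 31 at 0; 5.79% and 7.47% in single replicates). RRM2, a subunit of ribonucleotide reductase, was covered to 85.8%, at 0.57 ± 0.41, over an annotated span of 91.0 kb (list median 18.0 kb). That share applies to the whole annotated model. CDC6 was covered to 3.00% (30.6% in replicate 1), and AURKA (41.4% in replicate 1) and AURKB to 0. The list of macroH2A, PARP and chromatin partners had a mean of 3.45% (29 genes; 7.41% and 8.31% in single replicates), with EED at 38%, HDAC2 at 36.7% and BMI1 at 0. ATRX, on chromosome X, was covered to 100% in replicate 1 and to 0 in replicate 2.

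Against length-matched random lists the mean was lower for fibroblast genes (adjusted permutation p = 0.00295), ribosomal protein genes (0.0004), cell cycle genes (0.00415) and chromatin partners (0.0054). With circular shifts these 4 lists had adjusted permutation p = 0.0045 each. Circular shifts place regions in genes and intergenic sequence alike, and shifted means (27.3% for cell cycle genes) exceeded the 19.9% of all measured genes. A lower call against shifts alone therefore does not set a list apart from genes in general. Cell cycle inhibitors and p53 targets had a mean of 7.43% (20 genes; 12% in replicate 2 alone; adjusted permutation p = 0.121 against length-matched lists and 0.0216 with circular shifts), with GDF15 at 63.1%, CDKN1B at 45.2% and BAX and BBC3 at 0. By mean log2 ratio against length-matched lists, the cell cycle list (-1.13 against -0.94) was not past the threshold, adjusted permutation p = 0.322, and the list of cell cycle inhibitors and p53 targets (-1.48 against -0.88) was lower, adjusted permutation p = 0.0199.

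Gene families that sit in clusters split. By the mean, at an unadjusted p under 0.05, length matching called these families in 48% to 73% of 100 shifts of the regions. No family is special there, so the circular shifts are given beside it. Shifts also place regions in intergenic sequence, so a lower call against them does not set a family apart from genes in general. Neither null therefore settles a lower call for a clustered family. Zinc finger genes had a mean of 3.67% (476 genes), lower than length-matched lists (adjusted permutation p = 0.0004) and than circular shifts (0.0045). ZNF157 on chromosome X and ZNF114 were covered to 100%, and ZNF10 and ZNF100 to 0. All 53 clustered protocadherins were at 0, with PCDHA1 and PCDHA10 at a log2 ratio of -0.73 ± 0.03 (SD, n = 2), and 57 of 58 clustered histone genes were at 0, H2BC18 being at 79.5% and H1-1 and H1-2 at 0. Both families were lower than length-matched lists (adjusted permutation p = 0.0004) but not past the threshold with circular shifts (adjusted permutation p = 0.43 and 0.174), nor were histone genes by mean log2 ratio (-0.80 against -0.57 for length-matched lists, adjusted permutation p = 0.108). Keratin-associated protein genes had a mean of 43.6% (94 genes), higher than length-matched lists (adjusted permutation p = 0.0004) but not with circular shifts (adjusted permutation p = 0.377). KRTAP1-1 and KRTAP1-3 were covered to 100% and KRTAP10-1 and KRTAP10-10 to 0. Olfactory receptor genes had a mean covered share of 9.47% (386 genes), lower by both nulls (adjusted permutation p = 0.0004 and 0.0045), but their mean log2 ratio, -0.40, was higher than that of length-matched lists, -0.67 (adjusted permutation p = 0.00036). OR10A3 and OR10A6 were at 100% and OR10A2 and OR10A4 at 0. Neuronal and synaptic genes had a median of 5.53% (10.2% in replicate 1 alone), above the random median of 2.96% (adjusted permutation p = 1), and a mean of 13.8%, below the random 19.4% (adjusted permutation p = 0.174), while their mean log2 ratio, -0.36, was above the random -0.48 (adjusted permutation p = 0.296). With circular shifts the mean was lower than the 27.4% of shifted regions (adjusted permutation p = 0.0045) and the median lower than 22.2% (adjusted permutation p = 0.036). Shifts place regions in genes and intergenic sequence alike, so these 2 calls do not set the neuronal list apart from genes in general. GABRB1 was at 91.1%, GRIA4 at 64.1% and CSMD1 and CSMD3 at 0 (CSMD3 at 6.63% in replicate 1).

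**Figure D3:**
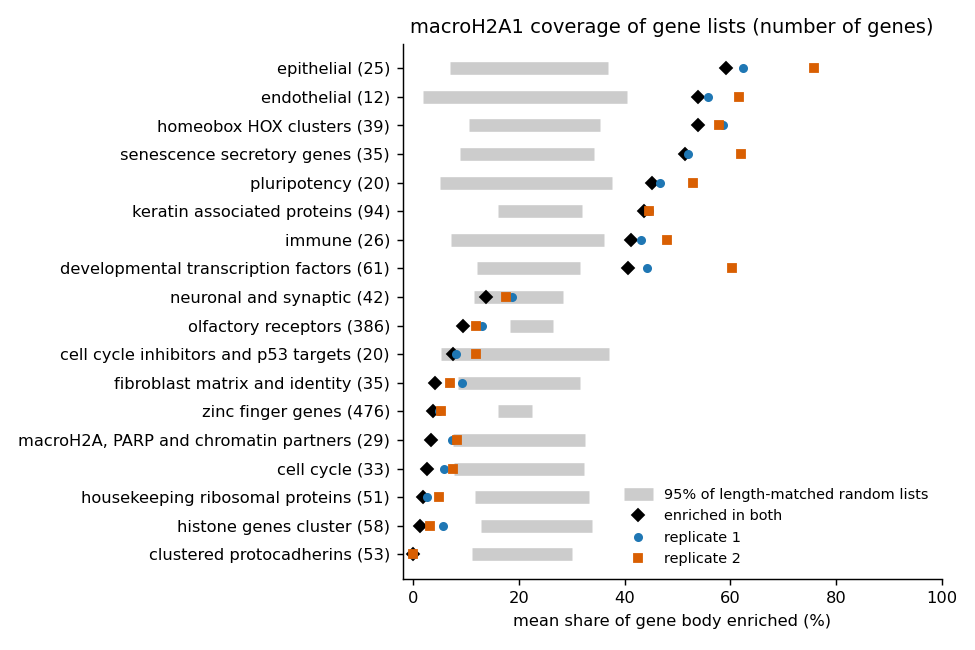
Mean percent of gene body in enriched segments (horizontal axis) for 18 gene lists, with the number of genes in parentheses. Diamonds show bases enriched in both replicates, circles replicate 1, squares replicate 2, and grey bars span 95% of 10000 length-matched random lists. Epithelial genes lie highest at 59.2% and clustered protocadherins lowest at 0.

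The log2 ratio of ChIP over input dropped sharply at start sites and stayed low into the gene. An input enriched in open chromatin near start sites stays open as an explanation. Over all protein-coding genes the mean log2 ratio was -0.31 and -0.28 in the 2 replicates 5 kb upstream, and -0.88 and -0.74 at the start site. It was still -0.77 and -0.71 at 20 kb downstream. Fibroblast genes went from 0.17 and 0.21 at 5 kb upstream to -1.70 and -1.31 at the start site, the steepest step of the lists plotted here. Ribosomal protein genes reached -2.01 and -1.63 at the start site and were already at -1.22 and -1.07 at 5 kb upstream. The senescence secretory genes lay at 0.85 and 0.81 at 5 kb upstream and at -0.04 and 0.04 at the start site. Epithelial genes showed no drop, with 0.04 and 0.37 at 5 kb upstream and 0.29 and 0.44 at the start site. These profiles are values without a test. Enriched segments had medians of 27.1 and 51.6 kb, so positions within a few kb are resolved only where a boundary falls.

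**Figure D4:**
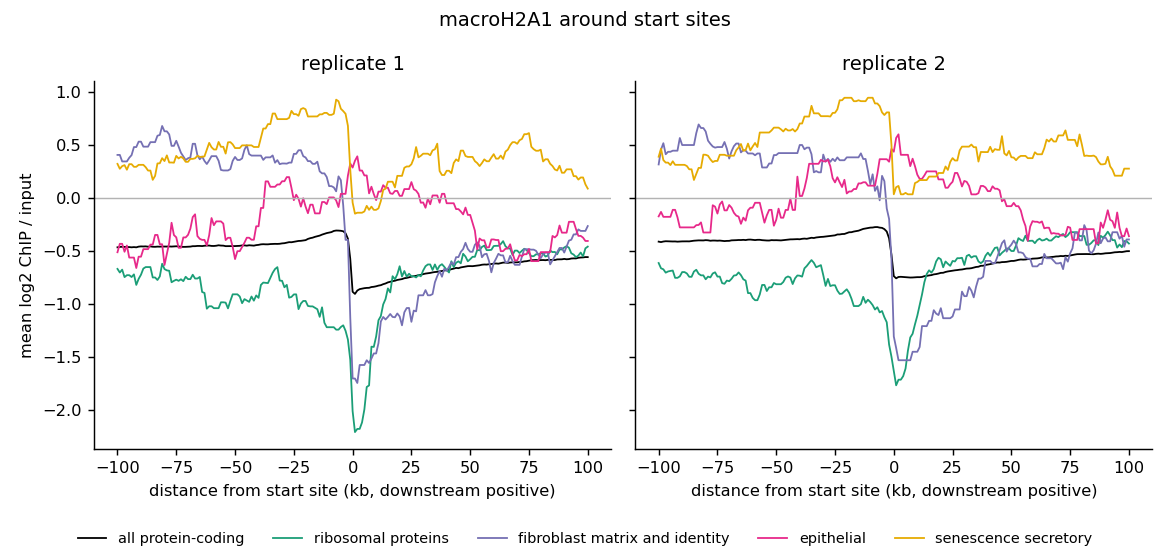
Mean log2 ratio of ChIP over input (vertical axis) by distance from the start site (horizontal axis, kb), for all protein-coding genes and 4 gene lists, in replicate 1 (left) and replicate 2 (right). Fibroblast genes fall from 0.17 and 0.21 at 5 kb upstream to -1.70 and -1.31 at the start site, and epithelial genes do not fall.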

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

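The thresholds −log10 p of 5 and log2 ratio over 0.5, autosomes alone and every setting with a mean were chosen after seeing the data. The megabase denominator was the planned one. The main cut-offs and the denominator of assayed bases were set once the files proved to be segmentations. The direction of the 4 annotation classes and of the GC difference, and their side of the threshold, were the same under every alternative run, and the Jaccard index stayed above shifted placement throughout. Merging segments within 5 kb left 9158 and 6280 regions and 1039 Mb in replicate 1. Requiring 50% overlap of both segments gave 32.7% and 60.8%.

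Chromosome X and the autosomes were covered to 15.2% and 8.71% by the stronger segments, 36.4% and 18.1% at log2 over 0.5, 61.5% and 24.9% over whole chromosome length, and 73.8% and 30.6% over megabases with an enriched region. At −log10 p of 5 the autosomes were at 23.9%. With single replicates chromosome X ranged from 69.4% to 75.4% and the autosomes from 31.4% to 33.4%, as fewer bases are enriched in both than in each.

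Against 7 lists higher and 0 lower, the stronger segments gave 0 higher, −log10 p of 5 gave 3 and log2 over 0.5 gave 3 (the HOX, senescence secretory, developmental and immune lists were lost at both), and circular shifts gave 0 higher and 1 lower. The 5-kb window at the start site gave 5 higher, without the immune and pluripotency lists, and autosomes alone 6, without the developmental list. The mean gave 8 higher and 8 lower, also when matched on GC, without replicate 1, without replicate 2 and on autosomes. The mean with circular shifts gave 2 higher and 8 lower, and the mean log2 ratio 9 higher and 6 lower. Of those 8, the neuronal list and the list of cell cycle inhibitors and p53 targets were not lower by mean share against length-matched lists. The neuronal list turned from above to below its null at 5.54% (median, circular shifts), 13.7% (mean, circular shifts), 13.8% (mean, mean matched on GC and mean on autosomes) and 17.6% to 18.7% (mean, single replicates). The cause was not tested. No paired analysis was possible because the inputs enter only through the authors' ratio. With 2 replicates and unknown depth, no call here measures variation between cultures.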

Other observations

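The tests of escape genes, of fibroblast gene bodies away from start sites and of the difference between the replicates were chosen after the results were seen, and the HOX paralog groups and the upstream flanks were also singled out then, with no prediction. HOX genes differed in coverage along a cluster. In HOXD the 6 genes of paralog groups 8 to 13 were covered to 100% (log2 ratio 0.60 ± 0.20, SD, n = 2) and the 3 genes of groups 1 to 7 to 9.04% (0.18 ± 0.09). In HOXC the 6 genes of groups 8 to 13 were covered to 100% and the 3 of groups 1 to 7 to 47.0%, with nearly the same log2 ratios, 0.45 ± 0.06 and 0.42 ± 0.43. In HOXB the means were 66.7% (3 genes, 0.18 ± 0.04) and 24.1% (7 genes, -1.63 ± 0.11). Genes within a cluster share segments, so they are not independent, and no test was made.

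Sequence upstream of fibroblast genes was enriched although the genes were not. From 10 to 50 kb upstream, the 35 fibroblast genes had a mean log2 ratio of 0.37 and 0.38 in the 2 replicates, where length-matched random lists averaged -0.38 (adjusted permutation p = 0.000514 over 18 lists, also when matched on GC). The start-site profiles had already shown these genes at 0.39 and 0.39 at 20 kb upstream and at 0.39 and 0.41 at 50 kb. The p-value therefore describes a pattern already seen and is no independent test of it. Length matching called 9 lists higher and 4 lower here, with HOX, endothelial and developmental genes 0.76, 0.77 and 0.64 above random lists and fibroblast genes 0.75. Circular shifts of the log2 ratios called 5 higher (fibroblast, senescence secretory, endothelial and developmental genes and chromatin partners) and 2 lower (ribosomal protein and zinc finger genes; adjusted permutation p = 0.00514 each), and HOX genes were not past the threshold (adjusted permutation p = 0.15). The senescence secretory list stood at 0.68 and 0.80 (random -0.48, adjusted permutation p = 0.000514), and chromatin partners, little covered in their bodies, at 0.22 and 0.28 (random -0.35, adjusted permutation p = 0.0027). Ribosomal protein genes were at -0.90 and -0.79 (random -0.51, adjusted permutation p = 0.0282), and cell cycle genes at -0.63 and -0.51 (random -0.47, adjusted permutation p = 0.745).

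The coverage of chromosome X was weighed against 2 technical explanations. A uniform gain of X DNA in the ChIP, as the only difference, would shift high and low bins alike. The X minus autosome difference at the 95th percentile was at most 0.0426 times that at the 5th, which argues against such a gain alone. The median bin differed by 0.95 and 0.78 in the 2 replicates, and X bins had a narrower spread. The percentiles cannot speak against a gain combined with a narrower spread. GC content would raise autosomal bins of the same composition, but these were covered to 26.7% against 66.9% on chromosome X. Chromatin of an inactive X that leaves out genes that escape inactivation stays open as a candidate: escape genes were listed from general knowledge after X coverage was seen, and only 25 of 37 had a value, under the limit of 80% applied after the outcome was seen, so the check is void; those 25 were covered to 14.7% on average (15.1% and 28.6% in single replicates) and 728 other X genes to 67.7% (72.5% and 77.2%), a difference of -53.0 percentage points (two-sided permutation p = 2e-05). That p-value has further limits. Neighbouring escape genes share segments (RAB9A and TRAPPC2 both had -1.06 ± 0.05), so the genes are not independent. Apart from RPS4X, the 25 lay at or before X:53449677, so escape cannot be told apart from position on the chromosome. KDM6A (-1.54 ± 0.02), KDM5C (-1.85 ± 0.25) and ZFX (-2.15 ± 0.24) were at 0, CTPS2, FUNDC1 and MED14 at 100%, and active transcription of escape genes in itself, untested here, may give the same contrast.

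For the differences between gene lists by mean share, GC content was argued against, since 100% of the 16 lists past the threshold stayed past it when random lists were matched on length and GC. That check used the mean, which length matching called too often for clustered families, and the 7 calls by the median were not matched on GC. An input enriched in open chromatin near start sites would lower the ratio there alone, but a segment carries a single value, so bases of a segment that reaches a start site cannot test this. Segments that touched no 5 kb around a start site were found in only 4 of the 24 fibroblast genes of 20 kb or more. In those 4 the mean log2 ratio differed from that of length-matched lists by -1.30 (permutation p = 0.0028), but with values for under 80% of the genes, the same limit, the check is void and this explanation stays open. No biological explanation was tested, as no expression data were used here.

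The replicates differed in a way that followed base composition. Across the 22 autosomes the replicate 1 minus replicate 2 log2 ratio fell with GC content, with a Spearman rho of -0.913 and a Pearson r of -0.908 (permutation p = 1e-05 each, the smallest these draws can give), and -0.886 and -0.873 without the 2 autosomes farthest in GC. A GC bias that differs between the libraries may account for this. Coarser segments in replicate 2 were predicted to leave chromosome means alike, and the differences of those means had an SD of 0.0863. That check cannot decide, because a mean of log2 values can itself change when unlike segments are merged. Coarser segments therefore stay open beside a GC bias. No biological explanation was tested, since the replicates are of 1 group.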
